A study of Mus musculus with 12 samples.

How the data were processed

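The measurement was droplet-based 5' single-cell RNA sequencing of lymph node B cells and plasma cells from 3 mice. Per the labels, cells of each mouse were marked with a barcoded antibody to CD45, pooled within the PC and the non-PC fraction and captured in separate wells. The labels list 12 libraries in 6 groups, with no file of their own, and every library names the same 3 mice. The deposited matrix pools all of them, and a deposited table gives the mouse, state, cluster, cell cycle call and scores of each cell. Cell Ranger and Seurat, without versions, and the builds mm10 and GRCm38 are named in the submitters' processing notes, with no role or order. Filters on cells and the treatment of doublets are not given in the sources used here.

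The deposited values are raw UMI counts per gene and cell, whole numbers whose sums per cell equal the totals in the deposited table, and no normalization had been applied. The scores per cell for dark zone, light zone, memory, plasma cell and activation signatures were computed by the authors, and the genes behind them are not given in the sources used here. The prePC state began at 0.251 of the plasma cell score, the preMem state at 0.780 of the memory score and the LZtoDZ state at 0.581 of the activation score, so each is part of a range. Of the LZtoDZ cells 32 lay within 0.02 above the boundary, and 39 other cells lay within 0.02 below it. Cells were named by state as deposited, and no cells were clustered again. The germinal center was the average of the DZ, LZ and LZtoDZ states.

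Raw counts were summed per mouse and state. Replicates are the 3 mice, never cells. Sums of fewer than 20 cells were left out, which kept prePC of mouse 2 (22 cells) and removed those of mouse 1 (17) and mouse 3 (10). All remaining sums entered 1 fit with state and mouse as terms, TMM scaling, filterByExpr and edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a state gave 1 sum, that sum was assumed to vary like the others. CPM values with SD are over 3 mice, use every cell of a state and are scaled by the TMM factors of the sums. CPM of single cells are scaled to the total of each cell instead, so CPM of sums and of single cells differ in scale. Errors of log2 fold changes are standard errors from the fit. Where the lower group had 1 to 3 UMIs, a ratio with an exact binomial 95% interval is given, and with 0 UMIs a lower bound against a floor of 3 UMIs over the group. These ratios and bounds pool the UMIs of all cells of a group, so the GC states weigh by their UMIs there instead of being averaged. The intervals and bounds cover counting error only. Where the lower group had 3 or fewer UMIs in the sums tested but more in all cells, the value over 3 mice is given.

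Of 27 gene lists with 375 members, 14 members were absent from the matrix. The 22 lists of B lineage genes were tested with camera at a correlation of 0.01 and with an estimated correlation. The other 5 lists, of T cell, NK cell, myeloid, stromal and erythroid transcripts, served to count cells with RNA of other types. Lck, Cd68 and Pecam1 were not counted there, since B cells or plasma cells of the matrix express them. With 2 or more such UMIs there were 33 DZ, 29 LZ, 4 LZtoDZ, 9 PC, 1 preMem and 5 prePC. Named genes were the 8 with the largest change in each direction past the threshold, with a mean of at least 50 CPM in the higher group and the same direction in 3 mice, leaving out immunoglobulin segments and predicted genes. Some genes that met this rule are not reported here. Prdm1, Xbp1, Irf4, Pax5, Bach2, Bcl6, Myc, Cxcr4, Sdc1 and Mki67 were given in each of the 4 planned comparisons, and for each list described the members with the largest changes past the threshold. Genes shown within single prePC were chosen after their values were seen. The groups, tests, lists and rules were fixed before the data were examined, except where a later choice is named.

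Same-numbered sums come from the same animal, so the mouse was a block in each fit. The pairing was checked on 4758 genes as the correlation of deviations from the state means, with a median r of 0.0942 over 30 pairs of sums of the same mouse (lowest -0.158) and -0.0521 over 60 pairs of different mice. Correlations of log expression between mice of a state ranged from 0.987 to 0.991 in DZ cells and from 0.885 to 0.897 in PC.

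Shares of cells are means and SD over 3 mice, compared with an exact two-sided sign-flip permutation test, which cannot go below 0.25 with 3 pairs. Cell cycle phase was taken from the authors' calls and, as an alternative, from the fixed S and G2/M lists after thinning cells to 1000 or 2000 UMIs. Thinning to 1000 left out 1 LZ cell, and thinning to 2000 left out 14 DZ, 20 LZ and 9 preMem cells. The isotype was that of the most abundant heavy-chain constant transcript, since B cell receptor libraries were not analysed here.

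The fit was tested on simulated counts with 200 changed genes. The counts were drawn from the real library sizes, the share of each gene pooled over all states and the dispersion trend of the fit. Apart from the changed genes, the simulated states did not differ in composition, and no mouse effect was included. The simulation therefore cannot test the assumption that the single prePC sum varied like the others. At the minimum of 20 cells the fit recovered 40.9% of genes changed 4-fold for prePC against GC cells (8527 genes tested) and 42.4% for PC against prePC (8557). The shares were 86.4% for preMem against GC cells (8491) and 92.4% for LZ against DZ cells (8475). False calls numbered 3, 2, 6 and 12 among 9002 unchanged genes, which include genes that the filter removed and that could not be called. At a minimum of 10 cells the shares for prePC against GC cells and PC against prePC rose to 75.8% (7970 genes) and 71.2% (7978). For 2-fold changes at 20 cells the shares were 10.4%, 2.99%, 50.7% and 83.6%, so small differences of prePC were mostly beyond reach.

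Alternatives fixed in advance were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, no replicate block, each mouse left out, immunoglobulin genes left out, Scrublet doublets left out, cells under 500 genes or over 10% mitochondrial UMIs left out, equal cell numbers, and fits of the compared groups alone except for LZ against DZ cells. A minimum of 10 cells, the top 5% of doublet scores left out, cells with other-type RNA left out, G1 cells only, the first barcode series only, LZ cells as the only reference, prePC of the pre-memory cluster only, the fit of LZ and DZ cells alone, LZ and DZ cells matched on UMIs, phase calls without immunoglobulin genes and the strict isotype call (at least 5 heavy-chain UMIs and 80% of them) were added after the data were seen, as were the comparisons of PC with GC, LZtoDZ with LZ and DZ, and prePC with preMem cells. Over 3 mice the minimum was 8 cells where cells were left out by doublet score, other-type RNA, phase or cluster, and 3 cells for the first barcode series. Scrublet called 0 of 5878 cells of the first and 5 of 122 cells of the second barcode series, so it had not worked, and the filter on genes and mitochondrial UMIs removed 0 cells, so neither says anything on stability.

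The planned comparison of sorted fractions was not run, since the labels tie no barcode to a fraction. No cycling PC state was annotated, so cycling and non-cycling PC were not compared. Somatic mutation and clonal sharing were not analysed here. Gene positions are from the GENCODE annotation of GRCm38. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5.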

Results

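B cells and plasma cells (PC) were taken from the draining lymph nodes of 3 mice immunised with NP-KLH, a hapten coupled to a carrier protein, in an oil-in-water type commercial adjuvant. The mice received tamoxifen by gavage, and cells were collected 5 days later, on day 16 of the primary response. Live cells that lacked IgD and carried the eYFP reporter were sorted, and PC and the remaining B cells were loaded into separate wells of a droplet-based 5' single-cell assay. The 12 libraries of the series fall into 6 groups, mRNA, hashtag and B cell receptor libraries of each sorted fraction, and the count matrix pools them. It holds unique molecular identifier (UMI) counts per gene in 6000 cells, and antibody hashtags marked the mouse each cell came from. The mice contributed 1491, 2079 and 2430 cells with 12669908, 18664942 and 20638376 UMIs.

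The authors' annotation divides the cells into 6 states. Germinal center (GC) B cells comprised 3040 cells of the dark zone (DZ), the region of proliferation and somatic hypermutation, 2213 cells of the light zone (LZ), the region of antigen capture and T cell help, and 165 cells annotated as moving from LZ to DZ (LZtoDZ). The other states were 396 pre-memory cells (preMem), 49 pre-plasma cells (prePC) and 137 PC. As a share of each mouse's cells, DZ cells made up 50.7% ± 1.60 (SD, n = 3), LZ cells 36.6% ± 3.37, preMem cells 6.66% ± 0.663, LZtoDZ cells 2.76% ± 0.104, PC 2.41% ± 0.924 and prePC 0.870% ± 0.399. The sort and the separate loading of PC set these shares. Median depth was 7052.5 UMIs per cell, from 4119 in preMem cells, 6258 in LZ and 7875 in DZ cells to 9225 in prePC, 19103 in LZtoDZ cells and 24018 in PC. Immunoglobulin transcripts took 36.4% of the UMIs of PC, 2.96% of those of prePC, 1.74% of those of preMem cells and between 0.817% and 1.46% in the 3 GC states. The cell barcodes fall into 2 series, of 5878 and 122 cells, that the labels do not tie to the sorted fractions. The second held 117 of the 137 PC, 2 prePC, 3 LZtoDZ cells and no other state.

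The prePC state held cells of different profiles, and this bears on every value given for it. By the authors' clusters, 40 of the 49 prePC lay in the cluster that also held 374 of the 396 preMem cells, and 9 lay in other clusters. Over single cells, the memory B cell list summed to a median of 4589 CPM (UMI counts scaled to the total of each cell) in the 40 cells and 667 in the 9, beside 3888 in preMem cells, 1101 in GC cells and 162 in PC. The list of unfolded protein response genes and endoplasmic reticulum (ER) chaperones ran the other way, with a median of 3388 CPM in the 40 cells and 9577 in the 9, beside 2413 in preMem cells, 2890 in GC cells and 20423 in PC. The list of PC surface and secretory markers differed less between them, at 5415 CPM in the 40 cells and 6245 in the 9, beside 2319 in preMem cells, 3183 in GC cells and 31953 in PC. Mki67, a marker of proliferation, was seen in 13 of the 40 cells and 8 of the 9. Over the 40 cells of the pre-memory cluster, median Hsp90b1 was 373 CPM, against 122 in DZ, 144 in LZ and 160 CPM in preMem cells. Median Xbp1 was 120 CPM against 95.9, 65.8 and 0, whereas median Jchain, which encodes the joining chain of polymeric antibody, was 202 CPM against 1375, 769 and 220. The state begins at a score of the authors, with 13 prePC within 0.02 above its boundary of 0.251 and 16 other cells within 0.02 below it. These divisions were examined after the values of the state had been seen.

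**Figure D1:**
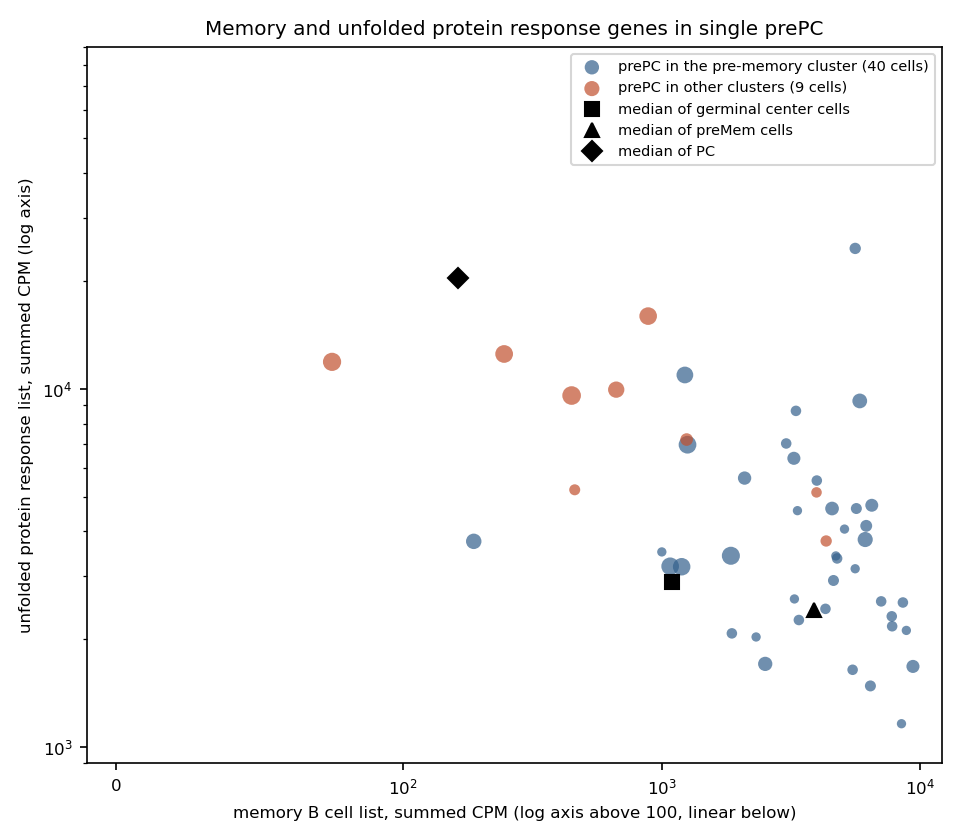
Each circle is 1 of the 49 prePC, with its summed CPM of the memory B cell list on the horizontal axis and of the unfolded protein response list on the vertical axis, and circle area rises with Jchain UMIs. The 40 cells of the pre-memory cluster (blue) had medians of 4589 and 3388 CPM, the 9 cells of other clusters (orange) 667 and 9577 CPM, and black symbols mark the medians of GC cells, preMem cells and PC.

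The first comparison asked how pre-plasma cells differed from germinal center B cells. In sums per mouse, prePC carried far more transcripts of genes of recirculating and memory B cells than GC cells did, more transcripts of ER chaperones, and fewer of the DNA replication machinery. Plac8, which encodes a small cysteine-rich protein, stood at 1546 ± 354 CPM in prePC (SD, n = 3) and 2.58 CPM in GC cells, a log2 fold change of 9.04 ± 0.41 (SE, adjusted p = 9.0e-07), and S100a10, the partner of annexin A2, at 970 ± 466 against 1.90 CPM (9.95 ± 0.22). Xbp1, the transcription factor of the unfolded protein response that PC require for secretion, rose from 111 ± 6.21 to 287 ± 30.1 CPM (1.18 ± 0.16, adjusted p = 1.2e-04). Its call was lost when immunoglobulin genes were left out (1.07, adjusted p = 0.284), when every mouse and state gave the same number of cells (0.99, adjusted p = 0.108) and when cells of the second of 2 barcode series were left out (0.55, adjusted p = 0.154). In that last setting the prePC sum of mouse 2 lost 1 cell and kept 21, and the GC cells lost 3 LZtoDZ cells of mouse 3. The drop from 1.18 to 0.55 thus came with the loss of 1 prePC, and is no test of the barcode series as a whole.

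Of 9230 genes tested, 595 were higher and 321 lower in prePC than in GC cells. The other genes with the largest increases were Ly6c2 (10.33 ± 0.78), the Ly6C surface antigen found on PC and monocytes, S100a6 (9.91 ± 0.63), Bhlhe41 (9.10 ± 0.75), a transcriptional repressor, Pml (8.43 ± 0.55), the scaffold of PML nuclear bodies, and Ccr7 (8.05 ± 0.67), the chemokine receptor that guides cells to the T cell zone. As medians over single prePC, Plac8 had 11 UMIs and S100a10 7, while Ccr7, Ly6c2 and S100a6 had 0, so the last 3 rested on a minority of the cells. S100a6 lost its call with equal cell numbers (8.48, adjusted p = 0.498). Among the largest decreases, Nuggc, a GTPase of GC B cells, changed by -2.19 ± 0.38 (adjusted p = 0.00158). Cpne5, a calcium-dependent membrane-binding protein, was 14.1-fold lower (counting interval 4.83 to 68.5, 3 UMIs in prePC), and Mybl2, a transcription factor of the cell cycle, 7.88-fold lower (2.69 to 38.3, 3 UMIs), against the pooled UMIs of GC cells. With the GC states averaged, the log2 fold changes over 3 mice were -3.42 for Cpne5 and -3.23 for Mybl2. Mybl2 lost its call with the DESeq2 Wald test (-2.74, adjusted p = 0.0694) and with equal cell numbers (-2.50, adjusted p = 0.055). Ell3, Amz2, Atad5, Pag1 and Lst1 had 3 or fewer UMIs in the pre-plasma sum that entered the test, where Atad5 and Pag1 lost their calls with the Wald test and with equal cell numbers, Pag1 also without mouse 1 and without cells holding other-type RNA, and Ell3 without mouse 3. Their values over 3 mice were -2.94 ± 0.49 for Ell3, an RNA polymerase elongation factor, -2.44 ± 0.39 for Amz2, -1.62 ± 0.49 for Atad5, which unloads the replication clamp, -1.57 ± 0.40 for Pag1 and -1.29 ± 0.35 for Lst1.

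The transcription factor Prdm1 (Blimp-1), which drives PC differentiation, missed the threshold at 4.95 ± 1.73 (adjusted p = 0.0688) and was seen in 5 of 49 prePC. Irf4, which also promotes PC fate, had 2.29 ± 0.81 (adjusted p = 0.0723), Bach2, a repressor of PC differentiation, -1.10 ± 0.35 (adjusted p = 0.0808), and Bcl6, the regulator of GC fate, -1.06 (adjusted p = 0.271). All 4 passed the test when the minimum was lowered to 10 cells so that 3 mice entered, with adjusted p = 1.9e-07 for Prdm1, 0.0112 for Irf4, 0.00217 for Bach2 and 0.0177 for Bcl6. Mki67 was lower in prePC (-0.83 ± 0.21, adjusted p = 0.0133), and over 3 mice (-1.01, adjusted p = 0.00107). At similar values it missed the threshold when immunoglobulin genes were left out (-0.92, adjusted p = 0.0629), without mouse 1 (-0.84, adjusted p = 0.0677) and with equal cell numbers (-0.73, adjusted p = 0.486), and against LZ cells alone it was smaller (-0.53, adjusted p = 0.178). Myc did not pass (adjusted p = 0.545). Other values that did not pass were -0.06 for Pax5, the factor of B cell identity (adjusted p = 0.976), -0.70 for Cxcr4, the chemokine receptor of DZ cells (adjusted p = 0.482), and 4.10 for Sdc1, the PC marker CD138 (adjusted p = 0.267).

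Grouped by the lists fixed in advance, 15 of 28 unfolded protein response and ER chaperone genes rose and none fell (16 when adjusted over the list alone), with Pdia4 at 2.49 ± 0.13, Hsp90b1 at 1.89 ± 0.15, Sdf2l1 at 1.70 ± 0.14 and Creld2 at 1.66 ± 0.22. Of 41 genes of ER translocation, glycosylation and early secretion, 12 rose (17 up and 1 down when adjusted over the list alone), among them Ssr4 (1.57) and Lman1 (1.25), although the list had adjusted p = 0.0884 with an estimated correlation. Of 14 memory B cell genes 10 rose and 1 fell (the same counts when adjusted over the list alone), with Cd38 at 6.02 ± 0.46, Klf2 at 5.65 ± 0.20 and Bcl2, an inhibitor of apoptosis, at 5.85 ± 0.77. Of 20 trafficking receptors and adhesion molecules 12 rose and 1 fell (13 and 2 when adjusted over the list alone), including the integrin chain Itgb7 (5.95). Of 14 PC surface and secretory markers 5 rose and 1 fell (7 and 1 when adjusted over the list alone), with Ly6a at 2.53, Txndc5 at 1.13 and Eaf2 at -1.33. Of 12 immunoglobulin constant regions 4 rose (7 when adjusted over the list alone), with Iglc2 at 2.17 and Ighm at 1.80.

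In the prePC of the pre-memory cluster alone, over 3 mice, 24 of 24 G2/M genes fell, with a median log2 fold change of -2.51. There 10 of 10 GC identity and 22 of 23 S phase genes fell, and 9 of 13 MHC class II genes rose. With an estimated correlation the lists had adjusted p = 0.0665, 0.0602, 0.0111 and 0.0818, in that order. Over all prePC of 3 mice the G2/M median was -0.77, and Mki67 went from -1.01 there to -2.92 in the cluster. In the prePC sum tested, given below, most S phase genes, and some G2/M and GC identity genes, were lower. Of 23 S phase genes 19 fell and none rose (21 when adjusted over the list alone), among them Gins2 (-1.93), Uhrf1 (-1.82), Pola1 (-1.79) and Hells (-1.64). Of 24 G2/M genes 5 fell (6 when adjusted over the list alone), including Ccna2 (-1.66) and Cdk1 (-1.63), with adjusted p = 0.244 for the list with an estimated correlation. Of 10 genes of GC identity 5 fell (7 when adjusted over the list alone), among them Rgs13 (-1.78) and Neil1, a DNA glycosylase (-1.56), with adjusted p = 0.116 with an estimated correlation. Only 2 of 13 genes of antigen presentation on MHC class II rose (3 when adjusted over the list alone), with Ctss at 0.95 and adjusted p = 0.201 with an estimated correlation. At least 2 UMIs of other cell types were found in 5 of the 49 prePC, a larger share than the 33 of 3040 DZ, 29 of 2213 LZ and 1 of 396 preMem cells, and 1 of the 5 held 64 UMIs of the myeloid gene Lyz2. Apoe stood at 678 to 1521 CPM in the prePC of the 3 mice against 133 to 459 CPM in DZ and LZ cells, with 182 UMIs in 1 prePC.

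The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment on counts summed per mouse and state, with the mouse as a block. Mice 1 and 3 had 17 and 10 prePC, under the minimum of 20 fixed in advance, so the prePC entered from mouse 2 alone and were assumed to vary like the other states. With a minimum of 10 cells, chosen after the cell numbers were known, 1646 of 8473 genes passed (938 higher, 708 lower), and 811 were called in the same direction in both. Restricted to the prePC of the pre-memory cluster, Pdia4 (2.84), Hsp90b1 (1.59) and Xbp1 (1.17, adjusted p = 2.3e-09) stayed above GC cells. Sdf2l1 (0.27, adjusted p = 0.423) and Creld2 (0.57, adjusted p = 0.153) did not. In these cells 8 of 28 unfolded protein response genes rose and 1 fell, with a median log2 fold change of 0.43 against 0.72 over all prePC. The list passed camera at the preset correlation (adjusted p = 0.00147) but not with an estimated correlation (adjusted p = 0.173).

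**Figure D2:**
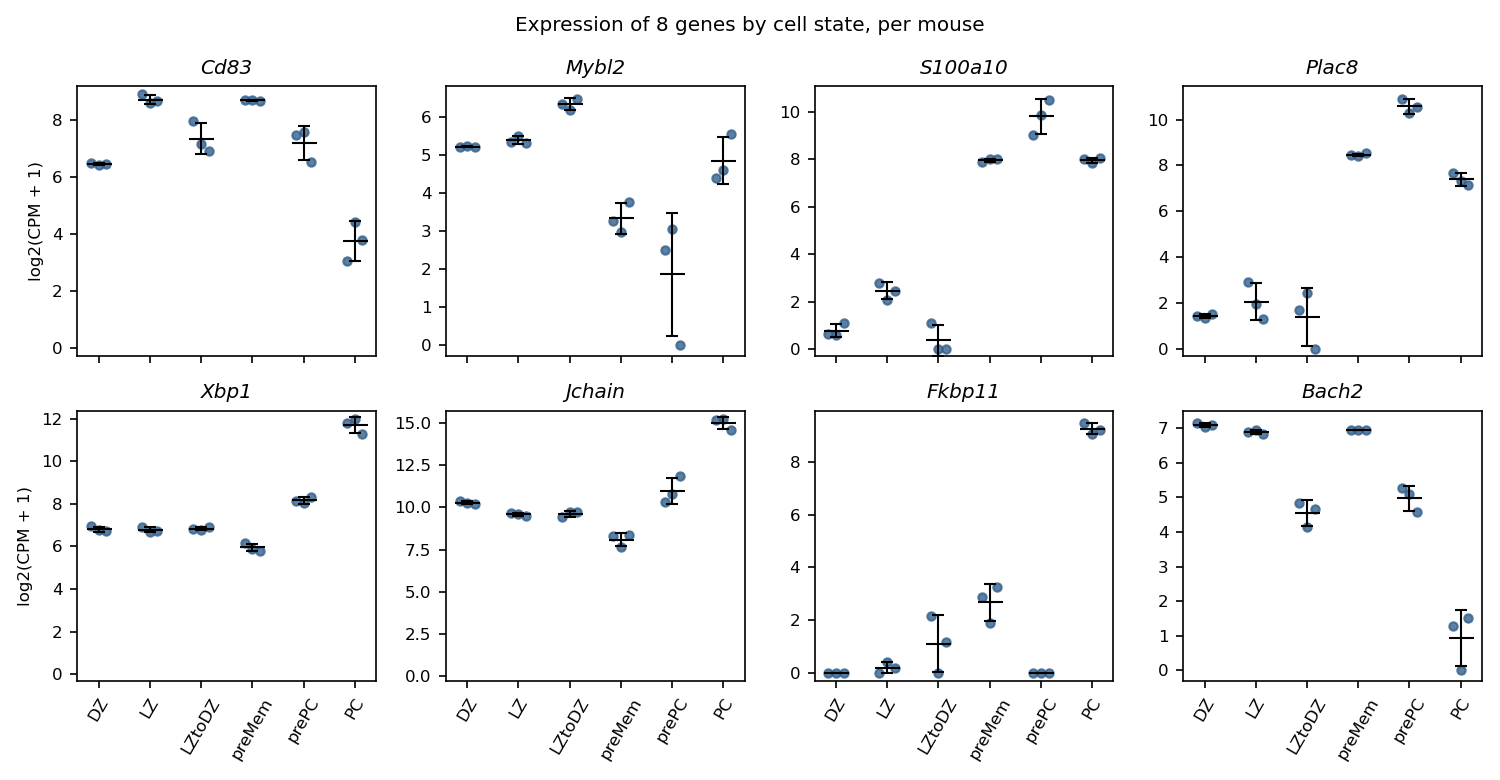
Points show log2(CPM + 1) of 8 genes in each of the 3 mice by cell state, with the mean as a bar and the SD as whiskers. S100a10 and Plac8 were higher in preMem cells, prePC and PC than in the 3 GC states, Xbp1 rose from a mean of 111 CPM in GC cells to 287 in prePC and 3369 in PC, and no UMI of Fkbp11 was seen in prePC.

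The second comparison asked what separated plasma cells from pre-plasma cells. As in the first comparison, prePC entered the test as the 1 sum of mouse 2, while CPM and SD are over 3 mice. Unless 3 mice are named, standard errors and adjusted p values therefore hold no spread of prePC between mice. Over 3 mice the log2 fold change of Xbp1 was 3.56 ± 0.15 (SE). PC had far more transcripts of the secretory machinery, of Xbp1 and Irf4 and of immunoglobulin genes, and had lost most transcripts of B cell regulators, class II antigen presentation and memory genes. Xbp1 reached 3369 ± 817 CPM in PC against 287 ± 30.1 in prePC (3.70 ± 0.22, adjusted p = 5.6e-09), and Irf4 reached 175 ± 30.1 CPM (2.99 ± 0.48, adjusted p = 1.2e-05). Fkbp11, a peptidyl-prolyl isomerase of the ER, had 1230 UMIs in PC and 0 in prePC and was at least 117-fold higher in PC (floor of 3 UMIs over the group). Sdc1 stood at 139 ± 16.4 CPM in PC, 80.4-fold above the single UMI in prePC (counting interval 14.3 to 3186). Prdm1 passed the test at 2.66 ± 0.87 (adjusted p = 0.0313) with 2 UMIs in the pre-plasma sum tested, and over 3 mice the difference was 0.76 (adjusted p = 0.227). It also lost its call with the DESeq2 Wald test (2.68, adjusted p = 0.0786) and without mouse 1 (2.63, adjusted p = 0.0535).

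Of 9230 genes, 763 were higher and 777 lower in PC than in prePC. Selm, a selenoprotein of the ER, was at least 31.4-fold higher and Bhlha15 (Mist1), a transcription factor of secretory cells, at least 17.4-fold higher, each with 0 UMIs in prePC. Bhlha15 (7.01, adjusted p = 0.602) and Hid1, a Golgi protein (6.63, adjusted p = 0.627), lost their calls with the DESeq2 Wald test. With 1 or 2 UMIs in prePC, the ratio was 46.2 for Alpl, an alkaline phosphatase (8.17 to 1835), 43.3 for Ckb, a creatine kinase (11.9 to 359), 42.8 for Creb3l2, a transcription factor anchored in the ER membrane (11.7 to 355), and 41.0 for Hid1 (7.25 to 1632). Rhob, a small GTPase, differed by 3.17 ± 0.59 over 3 mice, since the pre-plasma sum first tested had none of its UMIs. In the other direction Ms4a4c was 225-fold lower in PC (38.9 to 9006, 1 UMI), Nrgn 86.5-fold (28.5 to 429, 3 UMIs) and Hhex, a transcription factor of memory B cells, 39.8-fold (12.5 to 202, 3 UMIs). Nrgn lost its call without mouse 3 (adjusted p = 0.205) and without the filter on low counts (0.0717). Btg1, an antiproliferative gene, changed by -4.99 ± 0.51, S100a6 by -4.92 ± 0.60, the actin regulator Evl by -4.87 ± 0.34, the class II transactivator Ciita by -4.79 ± 0.54 and the protease inhibitor Serpina3g by -4.72 ± 0.48. With equal cell numbers S100a6 lost its call (-3.10, adjusted p = 0.612).

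The regulators of B cell identity were lower in PC. Pax5 changed by -4.16 ± 0.51, Bach2 was 33.3-fold lower (8.04 to 295, 2 UMIs in PC) and Bcl6 31.6-fold lower (4.38 to 1384, 1 UMI in PC). Myc (-1.38, adjusted p = 0.355), Cxcr4 (1.03, adjusted p = 0.186) and Mki67 (0.40 ± 0.23, adjusted p = 0.265) did not pass the test, and over 3 mice Cxcr4 did (1.08, adjusted p = 0.0446). Over 3 mice Mki67 stood at 0.61 (adjusted p = 0.0617). Against the prePC of the pre-memory cluster alone it was 2.50 ± 0.25 (adjusted p = 2.2e-09). Of 15 B cell and GC regulators 12 fell and 1 rose (14 and 1 when adjusted over the list alone), with Spib at -4.44, Bcl11a at -3.44 and Ebf1 at -3.05. Of 6 PC regulators 5 rose and 1 fell (5 and 1 when adjusted over the list alone), including Ell2, which promotes the secreted form of immunoglobulin mRNA (3.10).

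The secretory lists rose almost in full in PC. Of 41 genes of ER translocation, glycosylation and early secretion 38 rose (40 when adjusted over the list alone), with the oligosaccharyltransferase subunit Ddost at 3.42 and the translocon proteins Ssr2 and Ssr3 at 3.06 and 3.03. Of 28 unfolded protein response genes 24 rose (25 when adjusted over the list alone), with Dnajb9 at 4.34, Edem1 at 4.25, Hsp90b1 at 3.93 and Pdia4 at 3.54. Of 14 PC markers 13 rose, the same count as when adjusted over the list alone. Of 30 genes of oxidative phosphorylation 20 rose (21 when adjusted over the list alone), among them Uqcr11 (1.48) and Ndufa1 (1.44), with adjusted p = 0.0962 with an estimated correlation. Of 12 immunoglobulin constant regions 6 rose (6 up and 1 down when adjusted over the list alone), with Ighg1 at 5.89 and Igkc at 3.86. Of 23 S phase genes 4 rose (6 when adjusted over the list alone), among them Rrm2 (2.12) and Fen1 (1.41), with adjusted p = 0.172 with an estimated correlation. Against the prePC of the pre-memory cluster alone, over all mice, 15 of 23 S phase genes rose and none fell. Their median log2 fold change was 1.24, with adjusted p = 0.0267 for the list with an estimated correlation. There 19 of 24 G2/M genes rose and none fell, with a median of 2.18 against 0.18 with all prePC kept. The G2/M list had adjusted p = 0.0851 with an estimated correlation.

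Antigen presentation and memory genes fell in PC. Of 13 genes of class II presentation 9 fell (11 when adjusted over the list alone), with Cd40 at -4.15, H2-Oa at -3.86 and H2-Aa at -2.17. Of 14 memory genes 12 fell (12 when adjusted over the list alone), with Cd38 at -3.68, and Ccr7 (-4.40) fell among the trafficking genes. Of 18 genes of B cell receptor signalling 11 fell and 1 rose (11 and 1 when adjusted over the list alone), including Cd22 (-4.24) and Ms4a1, which encodes CD20 (-2.74), with adjusted p = 0.0669 with an estimated correlation. Of 18 NF-kB targets 12 fell (14 when adjusted over the list alone), including Il4i1 (-4.12), Cd83 (-3.81) and Rel (-3.05), with adjusted p = 0.0627 with an estimated correlation.

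PC and prePC came largely from different barcode series, since 117 of the 137 PC but 2 of the 49 prePC belonged to the second. Among cells of the first series alone, with 20 PC, 744 genes passed (274 higher, 470 lower). With a minimum of 10 cells 2302 of 8473 genes passed (1210 higher, 1092 lower), and 1389 were shared with the calls above.

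**Figure D3:**
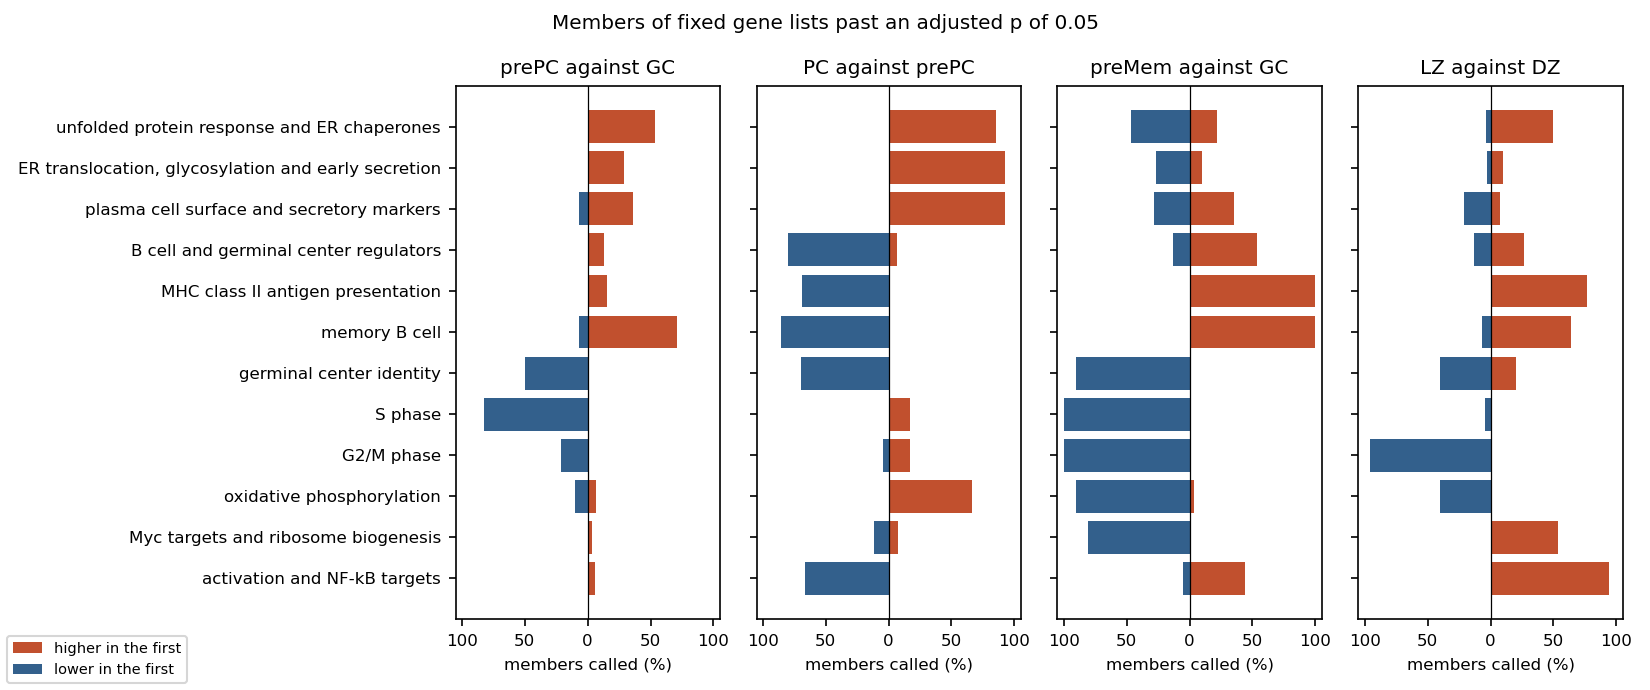
Bars give, for 12 fixed gene lists and 4 comparisons, the percent of tested members past the threshold, orange to the right for members higher in the first state and blue to the left for members lower in it. In PC against prePC 38 of 41 secretion genes pointed to the right, and in preMem against GC cells all 23 S phase genes pointed to the left.

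The third comparison set pre-memory cells against germinal center B cells. The preMem cells carried homing and memory receptors that GC cells almost lacked, more transcripts of antigen presentation and B cell surface genes, and fewer transcripts of proliferation, respiration and ribosome production. Ccr6, a chemokine receptor of memory precursors, stood at 214 ± 29.4 CPM against 2.03 in GC cells (7.27 ± 0.18), and Cd38 at 155 ± 26.7 against 3.07 CPM (6.52 ± 0.19). Other large increases were those of Pml (8.35 ± 0.25), S100a10 (7.92 ± 0.16), Plaur, the urokinase receptor (7.71 ± 0.41), Ccr7 (7.62 ± 0.35) and Plac8 (7.23 ± 0.29). As medians over single preMem cells, however, Ccr6, Ccr7, Cd38, Plac8 and S100a10 each had 0 UMIs at a median depth of 4119 UMIs. Mcm5, a subunit of the replicative helicase, stood at 54.1 ± 18.2 against 255 ± 1.81 CPM (-2.23 ± 0.13). Shmt1, an enzyme of 1-carbon metabolism, changed by -2.61 ± 0.32, Mybl2 by -2.41, Cdca7 by -2.40, the mitotic kinase Pbk by -2.37, Rcc1 by -2.35, Cdca3 by -2.32 and the kinetochore gene Nuf2 by -2.25.

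Of 9230 genes, 2364 were higher and 2015 lower in preMem cells. All 14 memory genes rose, as they did when adjusted over the list alone, with Klf2 at 6.22. All 13 genes of class II presentation rose (13 when adjusted over the list alone), with H2-Oa at 2.02, H2-Ob at 1.80 and Ctss at 1.46, though with adjusted p = 0.149 with an estimated correlation. Of 18 genes of B cell receptor signalling and surface 16 rose and 1 fell (16 and 1 when adjusted over the list alone), with Cd72 at 2.54, the inhibitory receptor Fcgr2b at 2.38 and Cd22 at 1.27, and adjusted p = 0.168 with an estimated correlation. Of 20 trafficking genes 14 rose and 2 fell (14 and 2 when adjusted over the list alone), and S1pr2, which holds B cells in the GC, changed by -1.52. This list had adjusted p = 0.0799 with an estimated correlation. Bach2 rose by 0.76 ± 0.10 (adjusted p = 2.3e-07) and Pax5 by 0.37 ± 0.11 (adjusted p = 0.00729). Against LZ cells alone Bach2 differed by 0.04 (adjusted p = 0.833) and Pax5 by 0.24 (adjusted p = 0.127). Pax5 also lost its call without mouse 2 (0.20, adjusted p = 0.289) and with equal cell numbers (0.51, adjusted p = 0.199). Of the lists above, 5 of 13 class II genes and 11 of 18 genes of B cell receptor signalling rose against LZ cells alone.

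All 23 S phase genes and all 24 G2/M genes fell in preMem cells, also when adjusted over each list alone. The G2/M list had adjusted p = 0.158 with an estimated correlation, and its members included Cdk1 (-2.11), Ccna2 (-2.07) and Cdc20 (-1.83). Of 26 Myc targets and ribosome biogenesis genes 21 fell (22 when adjusted over the list alone), with the spermidine synthase Srm at -1.76, Odc1 at -1.69 and Gnl3 at -1.66, and of 30 genes of oxidative phosphorylation 27 fell and 1 rose (27 and 1 when adjusted over the list alone), with Atp5b at -1.01. Both lists had adjusted p = 0.149 with an estimated correlation. The LZtoDZ state is 1 of 3 in the GC average, and against LZ cells alone 15 of 26 Myc targets fell, with Srm at -1.16, Odc1 at -1.30 and Gnl3 at -1.21, and 23 of 30 genes of oxidative phosphorylation fell and 1 rose. Of 10 genes of GC identity 9 fell (9 when adjusted over the list alone), among them Gcsam (-1.63), with adjusted p = 0.193 with an estimated correlation. Xbp1 changed by -0.89 ± 0.11 (adjusted p = 7.3e-06), Mki67 by -1.03 ± 0.12 (adjusted p = 4.7e-07) and Jchain by -1.74. No call was made for Bcl6 (0.03, adjusted p = 0.904), Myc (-1.03, adjusted p = 0.0916), Prdm1 (2.67, adjusted p = 0.0875, 3 UMIs in preMem cells), Irf4 (0.37, adjusted p = 0.58), Cxcr4 (-0.24, adjusted p = 0.303) or Sdc1 (1.36, adjusted p = 0.499, 1 UMI). The state begins at a memory score of 0.780, with 40 preMem cells within 0.02 above it and 46 other cells within 0.02 below it, and 35 of the 49 prePC also lay above it.

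The fourth comparison set light zone against dark zone cells. LZ cells had more transcripts of genes induced by activation and NF-kB signalling, and DZ cells had more transcripts of mitotic genes and of Cxcr4. Cd83, a marker of activated LZ B cells, stood at 424 ± 49.4 CPM in LZ and 87.0 ± 1.82 in DZ cells (2.27 ± 0.27, adjusted p = 3.2e-04), and Myc at 47.7 ± 9.31 against 16.2 ± 2.43 CPM (1.53 ± 0.23, adjusted p = 0.00109). Cxcr4 stood at 31.0 ± 3.06 CPM in LZ and 72.8 ± 6.46 in DZ cells (-1.23 ± 0.09, adjusted p = 1.3e-11), and Ccnb2, a mitotic cyclin, at 85.3 against 255 CPM (-1.59 ± 0.12). Il4i1, a secreted amino acid oxidase, had the largest increase (2.83 ± 0.51, adjusted p = 0.00403), which lost its call without mouse 3 (2.83, adjusted p = 0.114).

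Of 9230 genes, 1141 were higher and 913 lower in LZ cells. Other large increases were Fcer2a, which encodes CD23 (1.84 ± 0.23), the immediate early genes Egr1 (1.80 ± 0.12) and Ier2 (1.60 ± 0.10), the NF-kB inhibitor Nfkbia (1.78 ± 0.19), the adaptor Samsn1 (1.56 ± 0.09) and Lmo2 (1.55 ± 0.10). Large decreases were those of Rgcc (-1.92 ± 0.21), Myl4 (-1.67), the mitotic activator Cdc20 (-1.63 ± 0.13), Cdkn3 (-1.62), Pafah1b3 (-1.57), Nek2 (-1.40) and Knstrn (-1.35). Irf4 rose by 1.30 ± 0.25 and Prdm1 by 2.15 ± 0.54 (adjusted p = 0.00328), from 0.280 to 1.29 CPM, which lost its call without mouse 2 (adjusted p = 0.067) or mouse 3 (adjusted p = 0.0618). Myc also lost its call without mouse 2 (adjusted p = 0.0521). Mki67 changed by -0.63 ± 0.13 (adjusted p = 0.00127). Xbp1 (-0.04, adjusted p = 0.867), Pax5 (-0.16, adjusted p = 0.132), Bach2 (-0.20, adjusted p = 0.0579), Bcl6 (0.12, adjusted p = 0.218) and Sdc1 (-1.08, adjusted p = 0.528) did not pass.

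Of 18 activation and NF-kB targets 17 rose (17 up and 1 down when adjusted over the list alone), with Nfkb2 at 1.41. All 9 light zone genes rose, with Cd40 at 1.43 and Cd86 at 1.24, and all 7 dark zone genes fell, with the polymerase Polh at -1.29 and Gcsam at -1.24, and the counts were the same when adjusted over the list alone. These 3 lists each had adjusted p = 0.0708 with an estimated correlation. Of 24 G2/M genes 23 fell (24 when adjusted over the list alone), with Ube2c at -1.35, Cenpa at -1.33 and Ccnb1 at -1.31 and adjusted p = 0.0819 with an estimated correlation, whereas 1 of 23 S phase genes fell (1 when adjusted over the list alone). Of 13 genes of class II presentation 10 rose (11 when adjusted over the list alone), with H2-Oa at 0.99 and adjusted p = 0.134 with an estimated correlation. Of 26 Myc targets 14 rose (20 when adjusted over the list alone), with Srm at 0.77, and of 28 unfolded protein response genes 14 rose and 1 fell (14 and 1 when adjusted over the list alone), with Hspa5 at 0.73 and Txndc11 at -0.83. Both had adjusted p = 0.158 with an estimated correlation. Of 30 genes of oxidative phosphorylation 12 fell (16 when adjusted over the list alone), with adjusted p = 0.264 with an estimated correlation. In a fit of LZ and DZ cells alone 3336 genes passed, and among G1 cells alone 1107 did, where Cdc20 (-0.60, adjusted p = 0.202), Nek2 (-0.55, adjusted p = 0.195), Mki67 (-0.09, adjusted p = 0.653), Irf4 (0.75, adjusted p = 0.244) and Prdm1 (1.95, adjusted p = 0.114) lost their calls. Without mouse 3, 1159 genes passed, and Pafah1b3 did not (adjusted p = 0.0733). With equal cell numbers 118 genes passed, and Irf4 (0.31, adjusted p = 0.983), Egr1 (0.97, adjusted p = 0.336), Myc (1.12, adjusted p = 0.52), Cxcr4 (-1.95, adjusted p = 0.104), Nfkbia, Ier2, Samsn1, Lmo2 and Mki67 did not.

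The states were drawn by the authors from the same RNA, so genes that define a state separate it by construction, and the adjusted p values above are not independent evidence for the states. For the genes given without an adjusted p in the 4 comparisons, the adjusted p was under the threshold of 0.05 unless stated.

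The next comparison concerned proliferation, which the series names as a feature of plasma cell differentiation. By the authors' cell cycle calls, 89.4% ± 2.63 of LZtoDZ cells (SD, n = 3) were in S or G2/M phase, 64.5% ± 1.77 of DZ cells, 44.3% ± 4.11 of LZ cells, 34.5% ± 5.05 of PC, 13.8% ± 3.83 of prePC and 6.47% ± 1.97 of preMem cells. The share in PC exceeded that in prePC in 3 of 3 mice, by 20.7 points, with an exact two-sided sign-flip p = 0.25, the smallest that 3 pairs allow (adjusted p = 0.358 over 63 comparisons of shares). Of the 7 prePC called in S or G2/M, 6 were among the 9 cells outside the pre-memory cluster. Calls made from the fixed S and G2/M lists after thinning each cell to 1000 UMIs gave 34.3% ± 9.64 for PC, 21.3% ± 13.6 for prePC and 26.4% ± 2.63 for preMem cells. Thinned to 2000 UMIs, the shares were 32.8% ± 3.53, 12.4% ± 11.8 and 14.9% ± 0.733, so that the order of prePC and preMem cells depended on the calls, while the mean of PC lay above both in each. In mouse 2, however, 36.4% of prePC and 29.3% of PC were called after thinning to 1000 UMIs. Over single cells the S phase list had a lower median in PC (266 CPM) than in prePC (691 in the 40 cells and 1806 in the 9) and preMem cells (1107). A contribution of free RNA to these calls was not excluded.

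Isotypes were read from the most abundant heavy-chain constant transcript of each cell. A switched isotype was called in 82.4% ± 5.88 of PC (SD, n = 3), 45.8% ± 3.09 of LZ cells, 43.2% ± 3.55 of DZ cells, 41.4% ± 2.02 of LZtoDZ cells, 45.0% ± 18.0 of prePC and 16.2% ± 2.64 of preMem cells. Ighg1, the constant region of IgG1, led in 49.1% ± 17.8 of PC, 29.6% ± 8.15 of LZ cells and 14.6% ± 4.39 of prePC. Ighg2c led in 6.52%, 39.7% and 0% of the PC of the 3 mice, so the mice differed in their PC isotypes. Ighd led in 15.2% ± 2.73 of preMem cells although the sort took cells without surface IgD, and in 3.03% ± 5.25 (2 of 52 cells) where at least 5 heavy-chain UMIs and 80% of them were required. PC had a larger switched share than LZ cells in 3 of 3 mice (36.6 points) and preMem cells a smaller one in 3 of 3 (-29.6 points), each with an exact sign-flip p = 0.25, the smallest possible. Cells outside PC had a median of 4 to 12 heavy-chain UMIs against 374 in PC. Where at least 5 UMIs and 80% of the heavy-chain UMIs were required, the switched share was 81.3% in PC and 14.9% in preMem cells but 24.2% in DZ and 27.1% in LZ cells.

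The genes most used here to describe plasma cell differentiation are protein-coding and lie, on the GRCm38 assembly, at chromosome 11, 5520659 to 5525893 on the plus strand (Xbp1), chromosome 10, 44437177 to 44528501 on the minus strand (Prdm1), chromosome 12, 8771323 to 8793715 on the plus strand (Sdc1), chromosome 5, 88519809 to 88527891 on the minus strand (Jchain), chromosome 15, 98724366 to 98728198 on the minus strand (Fkbp11) and chromosome 15, 75108158 to 75111970 on the minus strand (Ly6c2). Counts refer to whole genes as the matrix names them. Ly6c2 belongs to a family of near-identical genes, and Ly6c2 counts may include reads of its close relatives.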

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

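The division by barcode series and each test on it were chosen after the cells of the series had been counted, and the dilution test also after its values had been seen.

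Of the 137 PC, 20 carried barcodes of the first series, which held 5878 cells in all, a division of the data that no planned comparison used. They numbered 3, 11 and 6 in the 3 mice. Immunoglobulin took 11.4% of their UMIs against 39.4% in the 117 PC of the second series, and their median depth was 15979.5 against 24606 UMIs. Of 3384 genes tested with edgeR's quasi-likelihood test, 325 were higher and 332 lower in the first series. Of 41 genes of ER translocation, glycosylation and early secretion 33 fell and of 27 unfolded protein response genes 19 fell, while 10 of 19 S phase genes and 5 of 6 memory genes rose. With an estimated correlation these 4 lists had adjusted p = 0.205, 0.205, 0.193 and 0.193.

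The lower immunoglobulin share of these PC may come from doublets of a PC and a GC B cell, from dilution of 1 PC profile by RNA of other cells, or from PC at an earlier stage, which the design does not test. Doublets predict GC genes that PC lack near the share a GC cell would bring, and 91 such genes had a median of 20.4% of their GC level (95% interval 16.7 to 25.7). That lay between the 30% set for doublets and the 15% set against them, and 5 of the 20 cells reached 30% or more, so this test did not decide. Mixed at that share with a PC like those of the second series, GC RNA would leave most of the immunoglobulin. Immunoglobulin instead took 5.57%, 13.8% and 10.6% of UMIs in the 3 mice, against 40.9%, 41.2% and 33.4% in the second series. This argues against RNA of GC cells, from doublets or dilution, as the whole cause, while a part in it stayed open. Dilution predicts an equal fall of every transcript that GC cells lack, and the 4 immunoglobulin genes fell further than 22 others, with a median difference of -1.22 log2 units beside an SD of 1.09 among those others. This passed the limit against dilution, but that limit was set after the values were seen. Only 1 of the 4 immunoglobulin genes lay under the 5th percentile of the others, so dilution by RNA of cells other than GC cells stayed open.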

How the results depend on the processing

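Every setting over 3 mice, and those that used a minimum of 10 cells, barcode series, cell phase, doublet scores, other-type RNA, UMI matching, the pre-memory cluster, LZ cells alone, LZ and DZ cells alone, phase calls without immunoglobulin or the strict isotype call, was chosen after the data were seen. Of 256 values of counts and shares under alternatives, 209 stayed within 1.5 times or 1 SD, and 47 moved. With 1 of 3 mice left out a share cannot move by 1 SD, so those values were bound to stay. The filter on genes and mitochondrial UMIs removed 0 cells and Scrublet called 5. Values under these settings, here and for the named genes below, could hardly move either. Of 1572 values of named genes, 1484 kept direction and side of the threshold, 49 lost and 26 gained a call, and 13 changed sign. Of 82 called genes and comparisons, 17 lost the call with equal cell numbers, 6 with the DESeq2 Wald test, 5 among G1 cells, 3, 3 and 5 without mice 1, 2 and 3, and at most 3 in each other setting that lost any. The cause was not tested where the setting does not show it.

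Equal cell numbers, which discard most cells, gave 446 genes for prePC against GC (370 higher, 76 lower), 908 for PC against prePC, 1381 for preMem against GC, 118 for LZ against DZ, 2276 for PC against GC, 1610 for LZtoDZ against LZ and DZ and 151 for prePC against preMem (117 and 34). Over 3 mice they gave 499 (341 and 158), 692 and 50 (34 and 16) for prePC against GC, PC against prePC and prePC against preMem. With a minimum of 10 cells prePC against GC had 1646 genes, from more mice, and prePC against preMem 362 higher and 314 lower. LZ against DZ had 3336 in a fit of both alone and 1107 among G1 cells, and LZtoDZ had 2550 after UMI matching, 2359 of them shared. Over 3 mice, G1 cells gave 448 and the fit of both groups 252 for prePC against preMem, and PC against prePC had 744 in the first barcode series and 1342 in the fit of both groups. The split moved by over 10 points for prePC against GC with the Wald test (755 and 206), and over 3 mice for prePC against preMem without a filter (284 and 384) or in the first series (245 and 405) and for prePC against GC in the pre-memory cluster (952 and 1161).

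With each mouse left out, counts ranged from 880 to 891 for prePC against GC, 1362 to 1438 for PC against prePC, 3317 to 3832 for preMem against GC, 1159 to 1604 for LZ against DZ, 4099 to 4346 for PC against GC, 3460 to 3875 for LZtoDZ and 486 to 581 for prePC against preMem. Without mouse 2 the prePC had no sum, and otherwise they were always the same sum of mouse 2. The narrow ranges of the comparisons with prePC therefore say little on stability. Over 3 mice the ranges were 1148 to 1317, 1560 to 1918 and 226 to 618 for prePC against GC, PC against prePC and prePC against preMem. Without the replicate block the counts were 977, 1615, 4453 and 1619 for the 4 planned comparisons and 5141, 4480 and 636 for the added ones, so the pairing moved none by over 1.5 times.

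With an estimated correlation 7 lists rather than 13 were called for prePC against GC, 3 rather than 10 for preMem against GC and 0 rather than 14 for LZ against DZ, and with a minimum of 10 cells as well 7, 4 and 2. The fry test called 18 for preMem against GC. The share in S or G2/M, by the fixed lists thinned to 1000 UMIs, to 2000 UMIs and unthinned, was 68.8%, 67.5% and 71.4% in DZ, 53.1%, 51.8% and 54.1% in LZ and 26.4%, 14.9% and 24.96% in preMem cells. In LZtoDZ cells it was 86.8% thinned to 1000 and 93.5% unthinned, and in prePC 21.3% thinned to 1000. With immunoglobulin left out it was 48.9% in LZ, 80.6% in LZtoDZ and 15.7% in preMem cells. The strict isotype call gave 24.2%, 27.1%, 30.1% and 26.7% switched in DZ, LZ, LZtoDZ cells and prePC, where few cells had 5 heavy-chain UMIs.

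Genes that changed sign had no call as reported. In preMem against GC, Bcl6 had -0.00403 without a filter, -0.0386 in the fit of both groups, -0.0223 in the first series and -0.41 against LZ alone, where it passed (adjusted p = 0.0405), and ranged from -0.13 to 0.178 with each mouse left out. Sdc1 ranged from -3.06 to 2.39 with each mouse left out and had -0.42 with equal cells. Cxcr4 ranged from -0.45 to 0.0416 with each mouse left out and had 0.17 against LZ alone. In LZ against DZ, Sdc1 ranged from -2.63 to 0.47 with each mouse left out, and Pax5 had 0.0830 with equal cells. Pax5 in prePC against GC had 0.0818 with equal cells and 0.0698 without cells holding other-type RNA. The cause was not tested.

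No value came from fits of both groups alone at a minimum of 20 cells for PC against prePC and prePC against preMem, where no degrees of freedom remained. None came from G1 cells for prePC at that minimum or for any comparison with the GC average, since too few LZtoDZ cells were in G1. Sorted fractions, cycling PC, somatic mutation and clonal sharing were not run. The prePC sum tested held 22 cells, and 40.9% of simulated 4-fold changes were recovered against GC cells.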

Other observations

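The comparisons of PC with GC cells, of LZtoDZ with other GC cells and of prePC with preMem cells, the tests of free plasma RNA, of the score boundary and of a mix of cells, and the counts of other splits were chosen after the results were seen.

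Compared with GC cells, PC had 2383 genes higher and 2637 lower of 9230 by edgeR's quasi-likelihood test. Xbp1 rose by 4.89 ± 0.09 on the log2 scale, Irf4 by 5.28 ± 0.16, Prdm1 by 7.61 ± 0.39 and Sdc1 by 9.30 ± 0.26. Tnfrsf17, the receptor BCMA that sustains PC, was at least 1074-fold higher and Bhlha15 at least 1611-fold, each with 0 UMIs in GC cells. Cd28 was 2852-fold higher (967 to 13904) and Entpd1, the ectonucleotidase CD39, 4503-fold (1237 to 37335). Of 28 unfolded protein response genes 27 rose and of 14 PC markers all 14, while all 10 genes of GC identity fell, with adjusted p = 0.0551 with an estimated correlation. Trafficking genes of both directions changed, with Itgb7 at 5.86 and Cxcr3 at 4.99 but S1pr2 at -4.25 and Rgs13 at -3.91. Oxidative phosphorylation rose in 25 of 30 genes, with adjusted p = 0.155 with an estimated correlation. The barcode series and the state were largely confounded here.

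The LZtoDZ cells differed from LZ and DZ cells by 2208 higher and 2287 lower genes. Myc stood at 125 ± 55.1 against 32.0 ± 5.78 CPM (2.09 ± 0.23), and all 26 Myc targets and ribosome biogenesis genes rose, with Srm at 2.97 ± 0.08, Gnl3 at 2.71 and the mitochondrial chaperonin Hspd1 at 2.14 (adjusted p = 0.0834 with an estimated correlation). Fabp5, a fatty acid binding protein, rose by 3.25 ± 0.12 and Batf by 2.72. All 18 genes of B cell receptor signalling fell, led by Cd79b (-1.54), as did 9 of 10 genes of GC identity, both with adjusted p = 0.163 with an estimated correlation. Bach2 (-2.48 ± 0.12) and Bcl6 (-1.16) also fell. In the comparison of prePC with preMem cells, prePC again entered as the 1 sum of mouse 2 unless 3 mice are named. Set against preMem cells, prePC had 387 genes higher and 205 lower. Xbp1 (2.07 ± 0.18), Jchain (2.68 ± 0.31), Sdf2l1 (2.87 ± 0.16), Creld2 (2.36), Slpi (3.09) and Ebi3 (3.34) rose. A few cells carried part of this, as median Jchain was 247 CPM over single prePC and 220 over preMem cells, and from all prePC of 3 mice to those of the pre-memory cluster Sdf2l1 went from 2.25 to 1.46 and Creld2 from 2.04 to 1.29, Slpi from 3.26 to 1.93, Jchain from 2.99 to 2.64 and Xbp1 from 2.22 to 2.09, whereas Ebi3 went from 2.52 to 3.05. In the sums first tested, 14 of 28 unfolded protein response genes rose with none falling (adjusted p = 0.0502 with an estimated correlation). Over 3 mice Ighd changed by -3.83 ± 0.37 and Cr2, the complement receptor, by -3.21 ± 0.57, and Ccr6 fell by 2.07 in the sums of at least 20 cells. Of 14 memory genes 3 fell and none rose.

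The sums of the prePC state held memory genes beside PC genes, and a mix of 2 kinds of cells in 1 state is a candidate explanation. In the 9 prePC outside the pre-memory cluster the memory list stood at 14.5% of its level in the other 40, under the 25% set for a mix, although the authors' clusters may rest in part on the same genes. A mix as the whole cause stayed open, since 25 of 43 PC and secretory genes called higher than in GC cells over all prePC (58.1%) stayed called in the 40 cells alone, Xbp1, Pdia4 and Hsp90b1 among them, with medians of 0.86 before and 0.57 after. RNA of other cell types was argued against for the 8 top named genes, as 8 of 8 stayed called within 1 log2 unit without cells that held such transcripts. Free RNA of plasma cells stayed open, since summed PC genes lay under the 99% Poisson interval expected from Jchain in 4 of 6 versions where all 6 were required, and so did the score boundary, as 35 of the 49 prePC lay above the memory boundary but the genes of the scores are not known.

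Within the pre-memory cluster the 5 prePC that were among the 10 with most Jchain had a memory list median of 1230 CPM, against 4770 in the other 35, while the unfolded protein response list stood at 3419 and 3360 CPM, above 2413 in preMem cells. The list of PC surface and secretory markers, which includes Jchain itself, stood at 14138 CPM in these 5 cells and 4904 CPM in the other 35.

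Deep cells taken by the activation score could raise Myc targets in LZtoDZ cells. After LZ and DZ cells were matched to them on UMIs, the list kept a median log2 fold change of 1.37 (1.63 before), with 25 of 26 genes higher and adjusted p = 0.0403 with an estimated correlation, which argues against depth as the whole cause. The match was incomplete for LZ cells, at a median of 14085 against 19103 UMIs, and was 19051 for DZ cells. The G2/M list did not keep its values, with a median of 0.18 before and -0.58 after. A boundary on an activation score that may itself hold Myc targets was not tested.

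In each comparison 6 sums of 3 mice can be split in 10 ways, too few for a share under 0.05. In all 7 comparisons 1 split, the real one, reached the real count. Every other split puts sums of both states in each group, so the difference between states adds to the spread there. Few calls were therefore bound to follow, and no conclusion is drawn from these counts. The real split and the highest other split called 1321 and 1 genes for prePC against GC, 1527 and 1 for PC against prePC, 4061 and 0 for preMem against GC, 3070 and 1 for LZ against DZ, 5273 and 0 for PC against GC, 4634 and 0 for LZtoDZ and 401 and 0 for prePC against preMem.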
